A study of Mus musculus with 29 samples.

How the data were processed

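RNA of 29 mouse samples was hybridized to Affymetrix arrays of 45101 probe sets, each sample on its own array. The labels give Trizol extraction, a spin column clean-up and biotin labelling by the manufacturer's protocol. The deposited values are intensity values on a linear scale, from 4.08 to 35997, with no normalization visible between arrays. The log2 medians of the arrays ranged from 4.94 to 7.09. How the probe set values were summarized, and whether a background was subtracted, are not given in the sources used here.

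The groups were taken from the strain labels: B6.Il4raQ576/Q576 (5 arrays, called Q576), B6.129Il4raR576/R576 (5, called R576), B6.Il4raQ576/Q576/IL-13tg (8) and B6.129Il4raR576/R576/IL-13tg (11). Genotype and labelled background are not separated by the design. The array numbers fall into 3 series, here called A (15 arrays), B (2) and C (12). No label says that they are batches. Replicate numbers follow the order of the deposited samples and carry no pairing.

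Values were quantile normalized over the 29 arrays with limma, raised to a floor at percentile 10 of the normalized table (log2 3.75) and taken as log2. Of the probe sets, 34958 were assigned to 1 gene symbol, 932 to several and 9211 to none, by the annotation supplied for the array. The symbols of 34754 probe sets matched the mouse reference table of assembly GRCm38.p6, which was used for gene names and gene order alone. Each of 18194 symbols was represented by the probe set with the highest mean. The 11825 genes above the table median (log2 6.19) in at least 5 arrays were tested.

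The fit was limma's linear model with the 4 groups and the array series as an additive block, with 23 residual degrees of freedom and moderated variances. Adjusted p values are Benjamini-Hochberg values of limma, two-sided, and a gene was called at an adjusted p under 0.05. The 5 contrasts were the transgene label within R576, the same within Q576, R576 against Q576 with and without the transgene, and the difference of the transgene effects. The fold changes are those of the fit, adjusted for the series, so they can differ from the differences of group means. A mean of both transgene effects was added after the values were seen.

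There were 33 gene lists for lung cell types, immune cells, IL-13 responses, other tissues and general processes, written from textbook knowledge. They were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Of these, 31 had a tested member, which gave 155 list tests over the 5 contrasts. Another 9 lists of nervous system cell types and regions were written after the values were seen. The level percentile of a gene is its place among the mean levels of all 18194 symbols.

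The text names up to 8 genes with the largest rise and 8 with the largest fall among those called in a contrast, and up to 3 members with the smallest p of each list described, whether or not they passed. It always names Il13 and Il4ra. These lists, contrasts, tests and rules were fixed before the data were examined. Other genes named were chosen after their values were seen: markers of tissues, Zscan22, Nat8l, Pgap2, Trim21, Pcdhb21, Ccl8, Slc18a3, Neurod2, the dim probe sets outside the comparisons, and the genes named in a contrast because another contrast called them.

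Relations of Il13 with list means used 100000 permutations, or all permutations for fewer than 10 arrays, Pearson's r and Spearman's rho, without Il13 in the mean of the list that holds it. Differences of array measures between groups and series were tested by permutation. Shares of genes near Il4ra were compared by Fisher's exact test, two-sided.

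Alternatives fixed beforehand changed the value scale, the floor, the centring, the series block, the arrays, the filter on dim probe sets, the probe set per gene, the variance model, array weights and thresholds, or left out each array in turn. After the values were seen, array classes were added as a block. The classes split series A into 9 arrays and 6 arrays, and kept series B and C. The 6 were drawn from their place on the first principal component. Their numbers are consecutive, but no gap in the numbers parts them from the 4 R576 arrays before them. Fits without a floor, without the filter on all probe sets, and without 8 arrays were also added then.

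The precision is limited by the number of arrays. The procedure was tested on simulated values, in which 200 genes of known change were planted. These values were drawn for each gene around its mean, with the residual spread of the fit. Unlike the arrays they held no series or array class effect and no relation between genes, so the rates describe that simpler setting. For the transgene label in R576 the procedure recovered 50.7% of changes of 0.25 log2, 88.1% of changes of 0.5 and 100% of changes of 1, with 8 false calls. At 0.25 log2 it recovered 58.2% for the transgene label in Q576, and 61.2% and 31.3% between genotypes with and without the transgene. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.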

Results

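The series holds 29 expression arrays of mice that carry either of a pair of alleles of Il4ra, the gene of the alpha chain shared by the IL-4 and IL-13 receptors. The strain labels are B6.Il4raQ576/Q576 and B6.129Il4raR576/R576, here called Q576 and R576, so the genotype groups are also labelled with different backgrounds. Part of the mice also carry an IL-13 transgene, and the series text names doxycycline treatment for the transgenic mice. There were 5 Q576 arrays, 5 R576 arrays, 8 arrays labelled Q576 with the transgene and 11 arrays labelled R576 with the transgene. The median intensity of an array ranged from 30.8 to 137 before normalization.

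Transcripts of the nervous system were among the brightest on all 29 arrays. The series text names lungs as the tissue, so the labels and the measured levels conflict, and the groups below are called by their labels alone. Mbp, the basic protein of myelin, was the brightest gene of the table, at a log2 level of 14.31 ± 0.07 (SD, n = 29). Nefl, a neurofilament subunit, stood at 13.51 ± 0.12 and Snap25, a synaptic protein, at 13.25 ± 0.11. Gfap, the intermediate filament of astrocytes, stood at 12.43 ± 0.12. Hoxa9, Hoxc8 and Hoxc10, Hox genes of posterior body levels, stood at 10.59 ± 0.18, 10.39 ± 0.12 and 9.41 ± 0.14. These genes were chosen after their values were seen.

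Surfactant and secretory transcripts of lung epithelium were dim on the same arrays. Sftpc, a surfactant protein of alveolar type II cells, had a level of 5.79 ± 0.06 (SD, n = 29), below the table median of 6.19 on every array. Sftpa1 stood at 4.32 ± 0.11, Sftpd at 4.60 ± 0.23 and Sftpb at 6.22 ± 0.40, above the table median on 7 arrays. Ager, a receptor abundant in alveolar type I cells, stood at 6.21 ± 0.09 and was above that median on 20 arrays. Scgb1a1, the main secretory protein of club cells, stood at 3.78 ± 0.10, beside a floor of 3.75. The median level percentile was 42.2 for the alveolar type II cell list, 51.2 for alveolar type I, 20.8 for club cell and 34.2 for ciliated cell. Of these 4 lists only club cell lay below the range of random lists of the same size (25.1 to 74.4), and 8 of 14 alveolar type II and 8 of 12 alveolar type I members were above the table median. The brightest members, Scd1 (12.15), Hopx (11.37), Tppp3 (12.01) and Aldh1a1 (11.93), are also expressed in other tissues. Among lists written after the values were seen it was 98.8 for neuron, 98.3 for astrocyte, 98.8 for oligodendrocyte and myelin and 73.2 for posterior Hox.

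**Figure D1:**
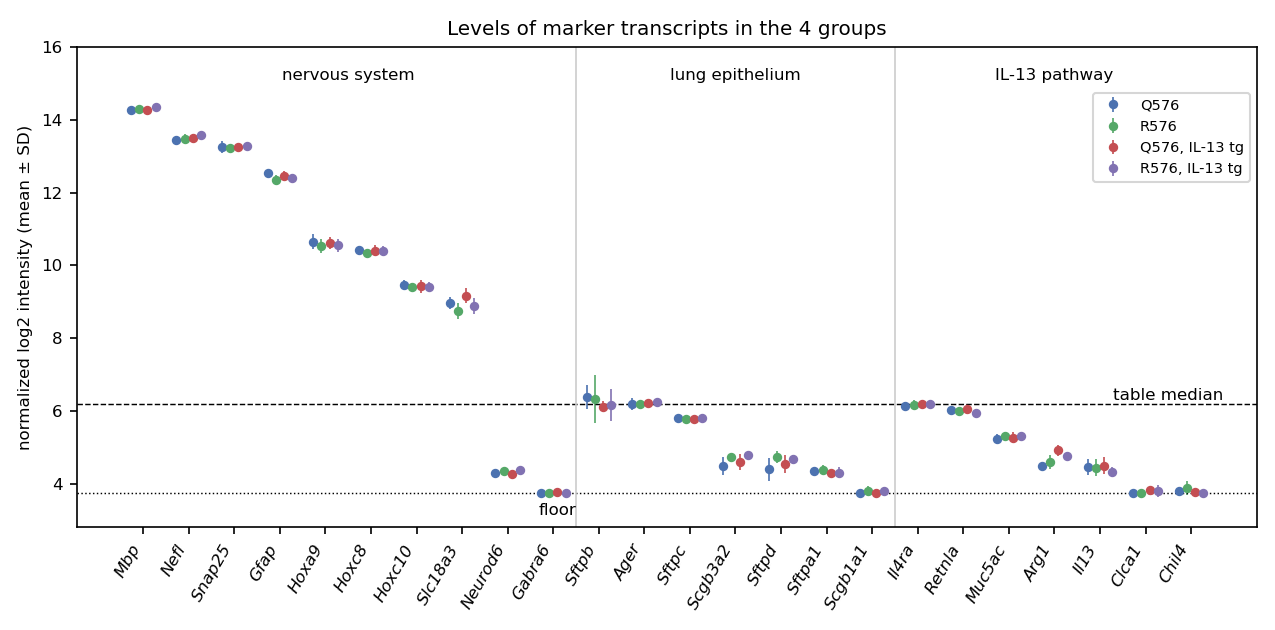
Normalized log2 intensity of marker transcripts (mean, bars SD) in the 4 groups of 5, 5, 8 and 11 arrays, with the table median and the floor as dashed and dotted lines. In every group Mbp lies above 14 and Scgb1a1 lies beside the floor of 3.75.

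Il13 itself was dim and was not tested. Its log2 level was 4.46 ± 0.21 (SD, n = 5) in Q576 arrays and 4.49 ± 0.23 (n = 8) in arrays labelled Q576 with the transgene. It was 4.44 ± 0.23 (n = 5) in R576 arrays and 4.32 ± 0.14 (n = 11) in arrays labelled R576 with the transgene. The fitted difference with the transgene label was -0.07 (SE 0.10) in R576 and 0.05 (SE 0.11) in Q576. The probe set does not tell a mouse transgene from the endogenous transcript. Il4ra had mean levels from 6.14 to 6.20 in the 4 groups, and its transgene effects were -0.03 (SE 0.05) in R576 and 0.02 (SE 0.06) in Q576.

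The arrays were alike over the whole table, with a lowest correlation of log2 values between any pair of 0.990 and a median of 0.995. The first principal component held 34.2% of the variance and set 8 arrays apart, namely both arrays of series B and the 6 arrays of series A with consecutive numbers. That class of 6 held Q576 replicates 1 to 3 and transgenic Q576 replicates 1 to 3, and no R576 array. The array median differed between the 3 series (permutation p = 1e-05, the smallest that the permutations can give; adjusted p = 0.000160), and the test between the 4 groups gave an adjusted permutation p of 0.0665. The log2 ratio of the 3 to the 5 prime control probe sets of Gapdh, a sign of RNA quality, was 0.21 ± 0.18 (SD) in the 2 arrays of series B. It was -0.13 ± 0.05 in the 15 arrays of series A and -0.17 ± 0.06 in the 12 of series C.

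**Figure D2:**
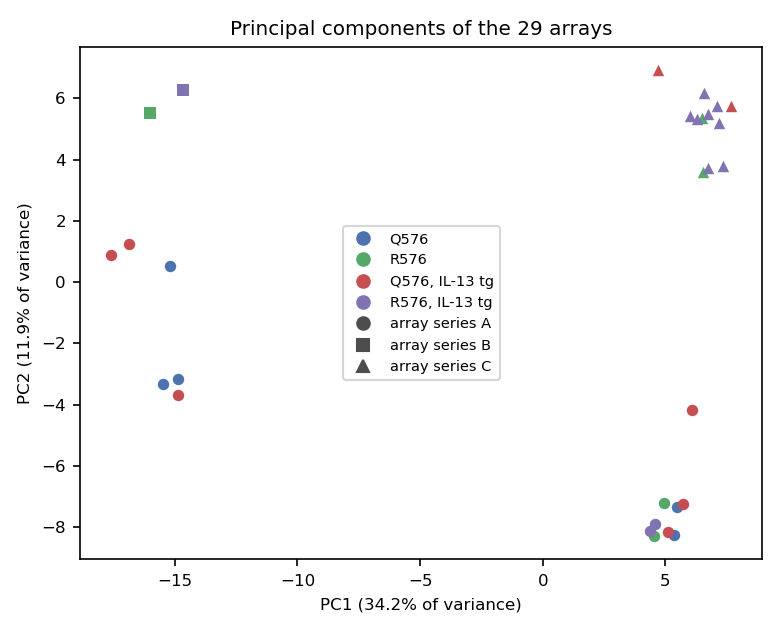
Position of each of the 29 arrays on the first and second principal components, with 34.2% and 11.9% of the variance; colours are the groups and symbols the array series. The 2 arrays of series B and 6 of the 15 arrays of series A lie at the left.

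The first comparison asks what the IL-13 transgene changes in R576 mice (11 transgenic arrays against 5). IL-13 drives mucus production, eosinophil recruitment and remodelling in the airways. The arrays are called by labels that conflict with the measured levels, so the directions below are those of the labels. Whether the mice without the transgene also had doxycycline is not stated plainly, so the transgene and the drug are not separated. Of 11825 genes, 7 passed, 3 higher and 4 lower in arrays labelled transgenic. Rimkla, a ligase of the neuropeptide N-acetylaspartylglutamate, rose by 0.77 (SE 0.10, adjusted p = 0.000380), from 10.04 ± 0.24 (SD, n = 5) to 10.75 ± 0.23 (n = 11). Inhba, the beta A subunit of activins and inhibins, rose by 0.43 (SE 0.07, adjusted p = 0.0109). Tmem88, a membrane protein, rose by 0.27 (SE 0.05, adjusted p = 0.0135). Igfbp5, a binding protein of insulin-like growth factors, had a log2 fold change of -0.34 (SE 0.04, adjusted p = 1.51e-05), from 10.27 ± 0.10 (SD, n = 5) to 9.91 ± 0.03 (n = 11). Msh3, a DNA mismatch repair gene, had -0.44 (SE 0.08, adjusted p = 0.0222). Mfsd4a, of a family of membrane transporters, had -0.39 (SE 0.07, adjusted p = 0.0135), and Ago1, an Argonaute protein of small RNA silencing, had -0.33 (SE 0.06, adjusted p = 0.0109). For each of the 7 genes all 11 transgenic arrays lay on the same side of the mean of the 5 others.

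At an unadjusted p under 0.05 there were 479 genes, where chance gives 591. In series A, with 2 transgenic arrays against 2, the fold changes were 0.71 for Rimkla, 0.44 for Inhba, 0.26 for Tmem88, -0.47 for Igfbp5, -0.22 for Msh3, -0.48 for Mfsd4a and -0.39 for Ago1. In series C, with 8 against 2, they were 0.85, 0.40, 0.36, -0.25, -0.57, -0.31 and -0.34 in the same order. Series B held 1 array of each kind. The count was 11 with the array classes as a block, 17 without the 8 arrays set apart, and 3 without R576 replicate 4 or without R576 replicate 5. On the deposited scale, without normalization between arrays, 0 genes passed in limma, and all 7 kept their direction with fold changes from -0.39 for Msh3 to 0.82 for Rimkla. A further probe set of Igfbp5, with a mean level of 7.04, differed by 0.03 (SE 0.08), and the further probe sets of Mfsd4a by 0.00 (SE 0.08 and SE 0.10) and -0.04 (SE 0.09).

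**Figure D3:**
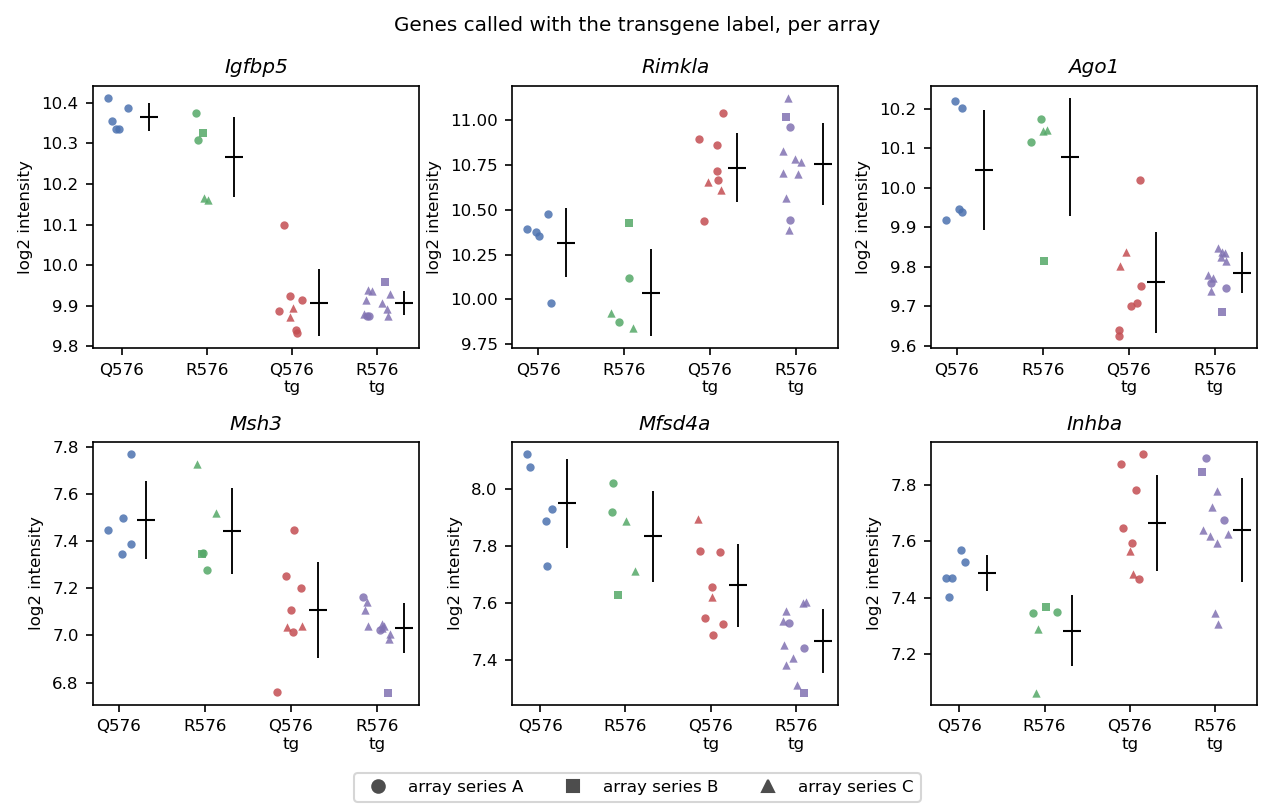
Normalized log2 intensity of 6 called genes on each array, by group (points are arrays, symbols the array series; bars are mean and SD of 5, 5, 8 and 11 arrays). Igfbp5 lies between 9.83 and 10.10 on the 19 arrays labelled transgenic and between 10.16 and 10.41 on the 10 others.

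The second comparison asks the same in Q576 mice (8 transgenic arrays against 5). Only Igfbp5 passed, with a log2 fold change of -0.45 (SE 0.04, adjusted p = 1.24e-07), from 10.37 ± 0.03 (SD, n = 5) to 9.91 ± 0.08 (n = 8). All 8 arrays labelled transgenic lay below the 5 others. Rimkla had 0.44 (SE 0.11, adjusted p = 0.560), Ago1 -0.29 (SE 0.06, adjusted p = 0.123) and Msh3 -0.39 (SE 0.09, adjusted p = 0.376), which did not pass. Inhba had 0.23 (SE 0.08, adjusted p = 0.999). At an unadjusted p under 0.05 there were 424 genes. Within series A (6 against 5) Igfbp5 had -0.45, series C held no Q576 array without the transgene, and with the array classes as a block 2 genes passed, Igfbp5 and Gpnmb. Without Q576 replicate 3 there were 2 genes, without transgenic Q576 replicate 3 there were 3, and with the arrays centred on their medians there were 0. On the deposited scale Igfbp5 had -0.39 and did not pass.

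Igfbp5 was the single gene called in both, where 0.000592 shared genes are expected by chance. Across the 11825 genes, which are not independent replicates, both sets of fold changes correlated with r = 0.145 and rho = 0.0948. Both contrasts share the series terms of the fit, so the correlation without any transgene effect need not be 0, and its value was not computed. Without the series term r was 0.362 and rho 0.332, and in draws of 5 arrays per transgenic group r ranged from 0.0693 to 0.325. The mean of both transgene effects, a contrast added after the values were seen, called 16 genes, 6 higher and 10 lower in the 19 arrays labelled transgenic. They include the 7 genes above. The others higher were Gpnmb, a glycoprotein of phagocytes (0.44, SE 0.09, adjusted p = 0.0256), Spsb4 (0.23, SE 0.05, adjusted p = 0.0243) and Htr2c, a serotonin receptor (0.23, SE 0.05, adjusted p = 0.0264). The others lower were Sox9, a transcription factor of glia and cartilage (-0.30, SE 0.06, adjusted p = 0.0301), Tbc1d20 (-0.25), Sfrp1, a secreted Wnt antagonist (-0.20), Tcea1 (-0.19), Tm2d2 (-0.18) and Pcbp2 (-0.16). A further probe set of Sox9, with a mean level of 7.80, rose by 0.36 (SE 0.05, adjusted p = 0.00159 over all probe sets). A further probe set of Tcea1, with a mean level of 9.90, had 0.08 (SE 0.03). Those of Tbc1d20, with mean levels of 7.07 and 4.30, had 0.01 (SE 0.05) and 0.04 (SE 0.07). The further probe sets of Tm2d2 lay between -0.08 and 0.04. With the highest-variance probe set per gene, a different probe set, the direction turned for Spsb4 (-0.18), Htr2c (-0.0385), Sfrp1 (0.11), Tm2d2 (0.0440) and Pcbp2 (0.0369). With each of the 29 arrays left out in turn, Tm2d2 stayed called in 7 fits, Sox9 in 18, Gpnmb and Spsb4 in 21, Htr2c in 22 and Pcbp2 in 23, and the count was 10 without R576 replicate 4 or 5. At an unadjusted p under 0.05 there were 574 genes, and the count was 26 with the array classes as a block and 2 on the deposited scale.

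No gene list passed in any of the 155 list tests, with camera at the preset or the estimated correlation or with fry. At an unadjusted camera p the mucus and goblet cell list had p = 0.00210 in R576, but it held 1 tested gene, Tff1, a trefoil factor (0.14, SE 0.04, adjusted p = 0.635; with 1 gene the list alone gives the unadjusted 0.00352). Of 5 tested genes of the alternatively activated macrophage and chitinase list, 0 passed over all genes. Adjusted over the list alone, Chil3 passed in R576 (-0.10, SE 0.03, 0.00811), and in Q576 Ccl17, a chemokine induced by IL-4 and IL-13 (0.25, SE 0.06, 0.00369), and Chil1 (-0.14, SE 0.05, 0.0262) passed. Of 13 tested genes of the IL-4 and IL-13 receptor signalling list, 0 passed by either count in either genotype, and Il13ra1 in R576 had -0.11 (SE 0.08), which became -0.01 without R576 replicate 3 or without transgenic R576 replicate 3, the arrays of series B. Of 22 tested TGF-beta family and growth factor genes, Inhba passed in R576 by both counts. Of 8 tested genes of the alveolar type II cell list, 0 passed with the transgene label, and Sftpb had -0.25 (SE 0.09, adjusted p = 0.999) in Q576. Without Q576 replicate 1 the Q576 values were -0.15 for Sftpb and -0.09 for Chil1, and without the 8 arrays set apart they were -0.01 and 0.02. On the deposited scale Chil3 had -0.02 in R576. In the macrophage and dendritic cell list Gpnmb passed over the list alone in R576 (0.47, SE 0.12, 0.00604) and in Q576 (0.41, SE 0.12, 0.0290). Oas1a of the interferon response list (-0.21, SE 0.06, 0.0277) and Casq2 of the heart muscle list (0.24, SE 0.09, 0.0457) passed over the list alone in R576. Rtkn2 of the alveolar type I cell list (-0.17, SE 0.05, 0.0404) did so in Q576. Adjustment over a list alone, here and below, does not correct for the 155 pairs of list and contrast. Some genes would thus pass in this way by chance.

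A pair of lists passed once dim probe sets were kept in the test, an alternative fixed beforehand. In R576 the mucus and goblet cell list was higher with the transgene label, with 12 of 15 members above 0 (camera adjusted p = 0.0178; adjusted p = 0.0525 with an estimated correlation). The chemokine list was also higher, with 19 of 27 members above 0 (camera adjusted p = 0.0115; adjusted p = 0.0291 with an estimated correlation). In Q576 it had 16 of 27 members above 0 (camera adjusted p = 0.330) and did not pass. Fcgbp, a mucus-associated protein, rose by 0.58 (SE 0.08, adjusted p = 0.00105) in R576 and by 0.51 (SE 0.08, adjusted p = 0.0117) in Q576. Agr2, a disulfide isomerase of mucin-secreting cells, rose by 0.29 (SE 0.06, adjusted p = 0.0316) and by 0.32 (SE 0.06, adjusted p = 0.0291). Ccl12, a monocyte chemokine, had 0.40 (SE 0.08, adjusted p = 0.0504) in R576 and 0.31 (SE 0.09) in Q576, and Ccl4 had 0.31 (SE 0.08, adjusted p = 0.222) and Cxcl5 0.17 (SE 0.05, adjusted p = 0.468) in R576. Ccl8, chosen after its value was seen, had the other direction in R576 (-0.17, SE 0.06, adjusted p = 0.513; adjusted over the list alone, 0.0239). In Q576 the mucus list had 10 of 15 members above 0 (camera adjusted p = 0.170, fry adjusted p = 0.0346) and did not pass in camera. Some of its members above 0 in R576 were near 0, as Muc5b (0.00464), Ern2 (0.00519) and Gcnt3 (0.0117). Slc26a4 had -0.09 (SE 0.08) in R576 and -0.20 (SE 0.08) in Q576, and Muc5ac had -0.02 (SE 0.07) in R576. These 5 members were chosen after their values were seen. The levels of the genes of both lists named here as higher were low, with 5.86 for Fcgbp, 3.97 for Agr2, 4.70 for Ccl12, 3.85 for Cxcl5 and 3.76 for Gcnt3. Agr2, Cxcl5 and Gcnt3 lay beside the floor of 3.75, which can limit a fold change. The mean transgene effect of Agr2 was 0.30 with the floor and 0.49 in a fit without floor or filter and with the array classes as a block. That fit changed several settings at once, so the part of the floor is not separated. With the array classes as a block the mucus list had a camera adjusted p of 0.0595 and the chemokine list 0.0142, or 0.0628 with an estimated correlation.

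**Figure D4:**
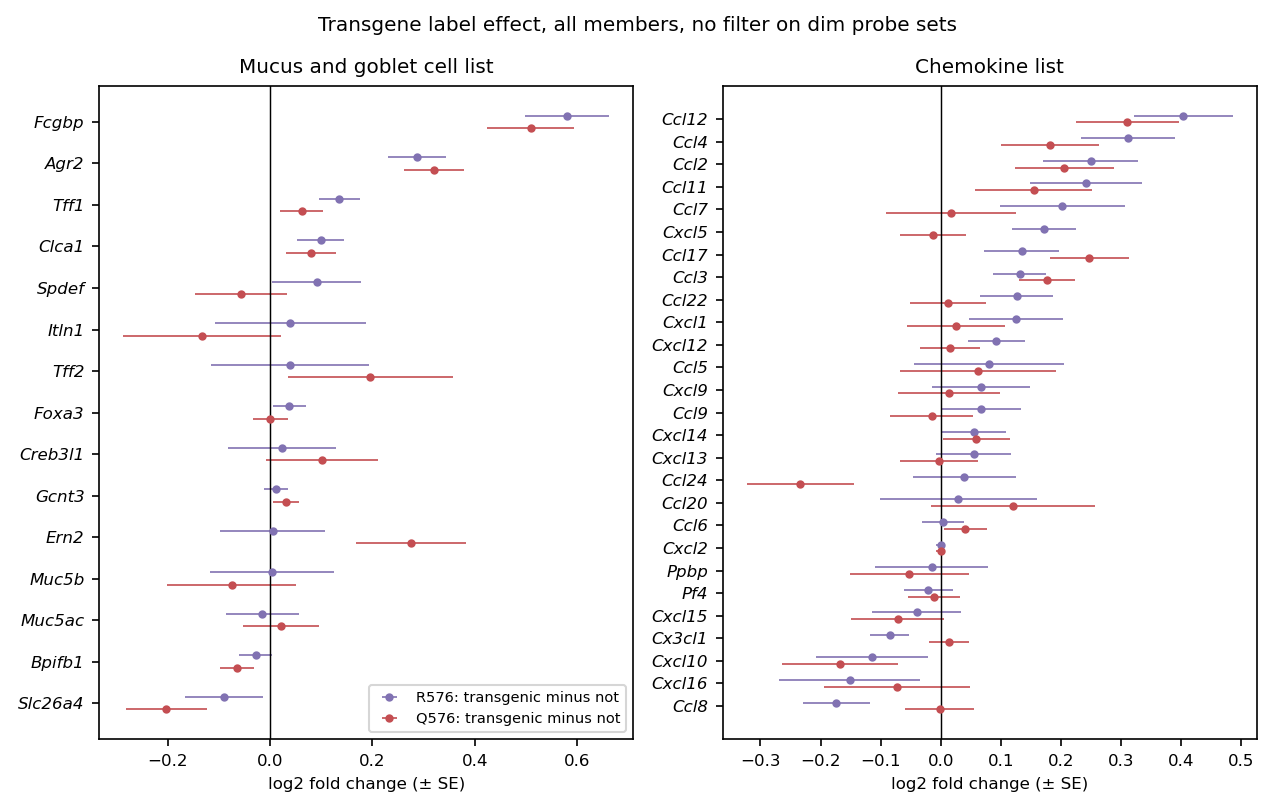
Fitted log2 fold change with the transgene label (bars SE) of each measured member of the mucus and goblet cell list and the chemokine list, with dim probe sets kept, in R576 (11 arrays against 5) and Q576 (8 against 5). Fcgbp and Agr2 lie above 0 in both genotypes.

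The third comparison asks how R576 and Q576 mice with the transgene differ (11 arrays against 8). No gene passed in limma. At an unadjusted p under 0.05 there were 888 genes, 446 higher and 442 lower in R576, where chance gives 591. The class of series A arrays set apart on the first principal component held 3 transgenic Q576 arrays and 0 transgenic R576 arrays. The fit had no term for this class, so the excess over chance cannot be read as a genotype difference. Zscan22 had the lowest adjusted p, 0.144, with a fold change of -0.45 (SE 0.08). Of the growth factor list, Hbegf, a ligand of the EGF receptor, had -0.14 (SE 0.03), which passed over the list alone at 0.00525 and not over all genes at 0.332. Of the receptor signalling list, Socs2, a suppressor of cytokine signalling, had -0.16 (SE 0.06, adjusted p = 0.647). Of the chemokine list, Cxcl14 had 0.15 (SE 0.05, adjusted p = 0.646). Rsph1 of the ciliated cell list (-0.18, SE 0.06, 0.0295) and Per3 of the clock list (-0.11, SE 0.03, 0.0390) passed over the list alone. Of lists written after the values were seen, Slc18a3, the vesicular acetylcholine transporter of motor neurons (-0.34, SE 0.10, 0.00995), did so. Neurod2, a neuronal transcription factor and the single tested gene of the forebrain list, had -0.28 (SE 0.11, unadjusted p = 0.0187, adjusted p = 0.647 over all genes). On the deposited scale the median of all genes shifted by -0.13 in both genotype comparisons, and Cxcl14 had 0.02, Hbegf -0.25 and Socs2 -0.27 there. Without the 8 arrays set apart Cxcl14 had 0.07 and Socs2 -0.11, and the highest-variance probe set of Hbegf had 0.00403. Series A gave 2 genes, Pgap2 and Trim21, and series C gave 1, Pcdhb21. Without Q576 replicate 4, transgenic Q576 replicate 7 or transgenic R576 replicate 11 there was 1 gene.

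Without the transgene, R576 and Q576 mice (5 arrays each) also had 0 genes past the threshold in limma, in a comparison that recovered 31.3% of simulated changes of 0.25 log2. At an unadjusted p under 0.05 there were 1310 genes, 633 higher and 677 lower in R576. The class of series A arrays set apart held 3 Q576 and 0 R576 arrays without the transgene. This count therefore cannot be read as a genotype difference either. Nat8l, the synthase of N-acetylaspartate, had the lowest adjusted p, 0.302, with a fold change of -0.42 (SE 0.09). Of lists tested alone, Sftpb had -0.32 (SE 0.11, 0.0429), Lcn2 -0.44 (SE 0.16, 0.0483) and Per3 -0.15 (SE 0.04, 0.0328), and these did not pass over all genes. Tff1 and Neurod2 were each the single tested gene of a list, so their p is unadjusted: -0.13 (SE 0.05, p = 0.0215 in limma, adjusted p = 0.435 over all genes) and -0.38 (SE 0.14, p = 0.0128 in limma, adjusted p = 0.428 over all genes). Chil1 had -0.14 (SE 0.06) and did not pass. Without the 8 arrays set apart Sftpb had -0.01 and Chil1 0.01, without Q576 replicate 1 Chil1 had -0.09, and without R576 replicate 1 Tff1 had -0.08. All 5 Q576 arrays and 2 R576 arrays were of series A, and 0 genes passed within it. With 4 runs of array numbers as the block, 1909 genes passed here and 1331 with the transgene, while with the array classes as the block 0 passed in both. In series A the R576 arrays shared a run only with Q576 arrays of the class set apart on the first principal component. Genotype and class thus coincide within that run. Among the Q576 and transgenic Q576 arrays of series A, 4498 genes differed between that class and the rest. The counts with runs therefore cannot be read as genotype differences. Genes that flank Il4ra can travel with an introduced allele. Of 77 tested genes among the 100 on each side, 0 passed; 7 had an unadjusted p under 0.05 (9.09%), against 11.1% of the other genes (Fisher's exact p = 0.716). With the transgene 7 of the 77 did so, against 7.50% (Fisher's exact p = 0.517).

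The test of the difference between both transgene effects called 0 genes in limma, and 299 had an unadjusted p under 0.05, where chance gives 591. Thus the calls made in R576 alone were not shown to differ from Q576. Inhba differed by 0.20 (SE 0.10, adjusted p = 0.999), Chil1 by 0.13 (SE 0.07, adjusted p = 0.999) and Il13ra1 by -0.20 (SE 0.12, adjusted p = 0.999). Sftpb differed by 0.26 (SE 0.12, adjusted p = 0.999). Without Q576 replicate 1 Chil1 had 0.08 and Sftpb 0.16, without either series B array Il13ra1 had -0.10, and without Q576 replicate 3 it had -0.13. Without the 8 arrays set apart all 3 were near 0, with 0.01 for Chil1, 0.01 for Sftpb and 0.01 for Il13ra1.

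Over the 19 arrays labelled transgenic the Il13 level was related to the mean of each of the 33 lists. The IL-4 and IL-13 receptor signalling list had r = 0.752 (permutation p = 0.000220, adjusted 0.0218) and rho = 0.746 (permutation p = 0.000510, adjusted 0.0505). The Th17 and IL-17 response list had r = 0.694 (permutation p = 0.000930, adjusted 0.0460) and rho = 0.653 (permutation p = 0.00329, adjusted 0.163). Without the 2 arrays farthest from the median Il13 level r was 0.700 and 0.663. Over 99 relations, pooled and within each genotype, 2 passed by Pearson's r and 0 by Spearman's rho. Within series A (8 arrays) the receptor signalling list had r = 0.766 and within series C (10 arrays) 0.628, and 0 of the relations passed in either series. The Il13 level was below the table median on every array.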

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

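An array was listed here when its value lay far from the other arrays of its group, a rule fixed before the data were examined. Over 52 genes and array measures, 165 groups were examined and 25 values were listed, where about 1 in 20 groups, or 8.25, is expected by chance. The 11 arrays labelled R576 with the transgene were not examined, as the rule did not take a group of that size. Of the 25, 11 came from R576 replicate 3, of series B, and 10 from the class of 6 series A arrays, so they are not independent. No array was left out for them.

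R576 replicate 3, of series B, held more of them than any other array examined. The other series B array, of the transgenic R576 group, was not examined. The log2 values of R576 replicate 3 were 9.81 for Ago1, 6.66 for Gpnmb, 8.67 for Chil1, 6.72 for Mrc1 and 6.87 for Stat6. That array also had 9.10 for Irs1, 10.15 for Jak1, 9.11 for Cxcl14 and 7.49 for Sftpb. The other R576 arrays without the transgene had Sftpb from 6.02 to 6.04. The 3 to 5 prime log2 ratios of R576 replicate 3 were 0.34 for Gapdh and 1.05 for Actb. Other R576 arrays listed were replicate 4 for Inhba (7.06) and replicate 2 for Cxcl16 (7.10).

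Q576 replicate 3 had 6.64 for Mrc1, 7.65 for Cxcl16, 7.49 for Cxcl1, 8.79 for Etv5 and an Actb ratio of 0.95. Q576 replicate 4 had 9.98 for Rimkla, where the other Q576 arrays lay from 10.36 to 10.48. Among transgenic Q576 arrays, replicate 2 had 7.96 for Tff1, 7.45 for Cebpa and an Actb ratio of 1.14. Replicate 3 had 10.10 for Igfbp5 and 6.89 for Stat6, and replicate 8 had 9.78 for Cx3cl1.

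Outside the 5 comparisons, a fit of all probe sets was added after the values were seen. It had no filter or floor and took the array classes as a block. For the mean transgene effect it called 87 of 45101. Of these, 66 were probe sets that did not enter the main comparisons, some of them further probe sets of genes that did. Among the 87, 57 were higher and 30 lower with the transgene label, and 52 had a mean level below the table median. Arg1, an enzyme induced by IL-13 in macrophages, had 0.31 (SE 0.05, limma adjusted p = 0.00634), Tnfrsf9 0.72 and Vsig1 0.61. These were dim, with mean levels of 4.73 for Arg1, 5.62 for Tnfrsf9 and 4.22 for Vsig1. A probe set of the chemokine Cxcl1 had -0.85 (limma adjusted p = 4.42e-07), while another rose by 0.36 (limma adjusted p = 0.00122). Chil4 had -0.03 (adjusted p = 0.975), Retnla 0.02 (adjusted p = 0.971) and Muc5ac -0.01 (adjusted p = 0.994).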

How the results depend on the processing

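Counts are given where they moved. In R576, 7 genes became 0 on the other value scale, 3 with arrays centred on medians, 2 without the series term, 1 in series A, 11 with only the 2 groups, 18 without the filter, 3 with a filter at percentile 75, 11 over all probe sets, 42 with array weights, 0 at a fold of 2 and 2 at an adjusted p under 0.01. Added after the values were seen: 11 with array classes, 11 with 5 blocks, 17 without 8 arrays, 31 with classes and no filter, 44 with all probe sets and no floor as well. In Q576, 1 became 0 centred, 10 without the filter, 5 with the highest-variance probe set, 5 over all probe sets, 2 with weights and 0 at a fold of 2; added, 2, 2, 8, 10 and 19 in the same order. With the transgene, 0 between genotypes became 1 without the series term, 1331 with 4 runs, 2 in series A, 1 in series C and 1 without the filter; added, 2 and 2 with classes and no filter. Without it, 0 became 1909 with 4 runs, 1 with the highest-variance probe set and 8 with weights. The difference of effects became 1 in series A. The mean effect, all added, went from 16 to 2 on the other scale, 8 centred, 2 in series A, 35 without the filter, 10 at percentile 75, 29 with weights, 0 at a fold of 2, 9 under 0.01, 26 with classes, 26 with 5 blocks, 37 without 8 arrays, 57 with classes and no filter and 87 with all probe sets. List tests went from 0 to 3 on the other scale, 2 without the filter and 1 with classes and no filter; with the estimated correlation these were 0, 1 and 0. The overlap went from 1 to 2 with classes; in draws of 5 arrays per transgenic group R576 had a median of 2 (0 to 7), Q576 1 (1 to 5) and the overlap 1 (0 to 3). Il13 relations went from 2 to 0 within series A and 0 within series C. With the highest-variance probe set, a different probe set, the mean effect reversed to 0.11 for Sfrp1, 0.0369 for Pcbp2, -0.18 for Spsb4, -0.0385 for Htr2c and 0.0440 for Tm2d2. Leaving out each array gave 3 to 7 in R576, 1 to 3 in Q576, 0 to 1 and 0 to 0 between genotypes with and without the transgene, 0 to 0 for the difference, 10 to 17 for the mean effect and 0 to 1 for lists. The cause was not tested. The counts with 4 runs cannot be read as genotype differences, because genotype and array class coincide in the shared run of series A. No paired analysis was possible because replicate numbers only follow the order of deposit. Signal near background limits what dim probe sets can show.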

Other observations

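The splits of the 5 comparisons fixed beforehand were planned before the data were examined, and all other tests in this section were chosen after the result was seen. Each comparison was refitted under 100 splits of its arrays, the real labels among them. In R576 only the real labels gave as many as 7 genes (1 of 100, highest other 1). This is under the limit of 5 fixed beforehand and argues against chance for the count. In Q576, 20 of 100 splits gave at least 1 gene (highest other 4281), so chance was not excluded for the count. For the comparisons with a real count of 0, any split gives as many (100 of 100), so the splits say nothing about chance there; their highest other was 2 between genotypes with the transgene, 883 without it and 1186 for the difference of effects. For the mean transgene effect 2 of 100 splits gave 16 or more genes (highest other 1634). This contrast and its limit of 5 were set after the values were seen, so no conclusion about chance is drawn.

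Nervous system transcripts were bright on every array and lung surfactant and secretory transcripts mostly dim, with Mbp at 14.31, Aldoc at 14.06, Cplx1 at 13.88 and Mobp at 13.80 among the 7 brightest genes, beside the widely expressed Fth1 (14.29), Gnas (13.85) and Cox5b (13.81). Probe set names out of step with the values are argued against by a Spearman correlation of 0.476 between the levels of both probe sets of 4694 genes, where the highest value after shuffling the pairs was 0.0498. The median level percentile of 6 lung secretory transcripts was 19.7, but they were chosen after the values were seen. Of the lung cell lists fixed beforehand, club cell (20.8) lay below the range of random lists. Alveolar type II (42.2), alveolar type I (51.2) and ciliated cell (34.2) lay within it. These values do not decide whether lung RNA was mixed with some nervous system RNA, and no conclusion is drawn. RNA of spinal cord in place of lung could give this pattern. The lowest median percentile of the neuron, astrocyte, myelin and posterior Hox lists was 73.2, while the forebrain list had 5.60. The other nervous system lists had 81.6 for peripheral nerve, 59.5 for motor and glycinergic neuron, 55.1 for microglia and 22.6 for cerebellum. The nervous system lists, posterior Hox among them, were written after the bright genes were seen, so they restate the pattern and do not test its source. Whether samples, files or labels were exchanged stays open.

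The 16 genes of the mean effect followed the transgene label. With the array classes as a block 16 of 16 stayed called. The class of 6 held 3 Q576 and 3 transgenic Q576 arrays, and series B held 1 array of each label. Both were thus spread evenly over the transgene label, so this test could hardly have turned out otherwise, and no conclusion is drawn from it. Lung RNA carried into the transgenic arrays is argued against by a median change of 0.00418 for the 6 lung secretory transcripts. Their changes ran from -0.12 for Sftpb to 0.07 for Scgb3a2. They were dim, with Scgb1a1 beside the floor, and were chosen after the values were seen, so a small share of lung RNA is not excluded. The rises of Fcgbp and Agr2 could come from a low response to IL-13 in the tissue sampled, with counts of 18 and 10 genes without the filter, but Il13 was not called and this was not tested. Doxycycline, if only transgenic mice had it, or a genetic difference near the transgene could also move these genes, and which holds stays open. For Igfbp5 0 transgenic arrays lay within the range of the others, but it was chosen for that separation and a full exchange of labels would look the same, so exchanged labels stay open.

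A class of 6 series A arrays lay apart from the others on the first principal component. Within the 11 Q576 and transgenic Q576 arrays of series A, 4498 of 11825 genes differed between that class and the rest. The class was drawn from this same separation, so the count restates it and does not tell a difference between array batches from another cause. The class may also explain the many calls in some Q576 splits, as with the classes as a block the highest other split fell to 660 from 4281 and 13 of 100 reached the real count of 2. What set these arrays apart is not given in the sources used here.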
